A study of Mus musculus with 18 samples.

How the data were processed

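RNA was sequenced from mouse TgSpi1 erythroleukemic cells with a doxycycline-inducible hairpin against Spi1, in 18 libraries of 6 groups with 3 libraries each, described by the labels as biological replicates. Per the submitters' protocol text, polyadenylated RNA went into an unstranded library kit, so overlapping genes on opposite strands cannot be told apart. The deposited tables hold raw counts per gene from the authors, 1 table for each of 2 experiments. Per the submitters' processing notes, bcl2fastq 2.17.1.14, STAR, DESeq2 and the mm10 genome were used; the notes give no roles, counter or annotation. The experiment 1 table lists 25628 genes by symbol with no value under 1, and 3543 genes at 1 in every library. The experiment 2 table lists 26903 genes by Ensembl identifier. Totals were 82.7 to 114 M counts in experiment 1 and 43.1 to 48.9 M in experiment 2. Reads without molecular identifiers are not independent molecules, so counts carry more than counting error, and the tests rest on the spread between libraries.

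Symbols, coordinates, transcript length and GC content came from GENCODE release M21 for mm10, which held 24876 of the symbols of experiment 1 and 26853 of the identifiers of experiment 2. Each experiment was fitted on its own with edgeR 4.0.16 in R 4.3.3, using quasi-likelihood fits on group means, TMM factors and filterByExpr, which kept 13811 genes in experiment 1 and 15051 in experiment 2. The common biological coefficient of variation was 0.194 and 0.242. Tests were two-sided, adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Experiment 1 gave 1 contrast from 6 libraries. Experiment 2 gave 5 contrasts from 1 fit of 12 libraries: doxycycline in DMSO, doxycycline in entinostat, entinostat without and with doxycycline, and their interaction, which is the doxycycline effect in entinostat minus that in DMSO. Lists with 5 or more tested members were tested with camera in limma 3.58.1, with a preset correlation of 0.01, adjusted over the lists of a contrast, and with an estimated correlation as an alternative. Overlaps of calls used the 12638 genes tested in both experiments as background and a two-sided Fisher's exact test, which takes genes as independent. CPM values are TMM-scaled.

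The contrasts, alternatives, gene lists and rule for named genes were set before the data were examined, apart from those said to be added. The 31 lists covered globin and heme synthesis, red cell membrane and surface, erythroid transcription factors, stem and progenitor regulators, macrophage and myeloid SPI1 targets, neutrophil granule, mast cell and basophil, megakaryocyte and platelet, B cell, T and NK cell, and stromal and endothelial genes. They also covered PRC2 subunits, HDAC and corepressor subunits, genes known to rise with HDAC inhibitors, replication-dependent histones, S phase, G2 and mitosis, cell cycle inhibitors, p53 targets, the BCL2 family, interferon-stimulated genes, immediate early genes and EPO and STAT5 response genes. The remaining lists were ATF4 and stress response, mitochondrially encoded, cholesterol synthesis, glycolysis, neuronal REST targets, HOX and developmental PRC2 targets, ETS factors, and chemokines and cytokines. The lists come from general knowledge and not from these samples.

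Named genes followed a rule. It took 14 fixed genes in every contrast. Among called genes with a mean of at least 5 CPM, no overlap between groups and a regular gene name, it took the 10 largest rises and 10 largest falls in experiment 1 and in entinostat without doxycycline, and 5 and 5 in the others, with overlap allowed in the interaction. It added up to 4 members with the smallest adjusted p of each list that passed or had more than 1 in 4 members called one way, and the 10 genes with the largest summed fold changes among those up in experiment 1 and with entinostat. Near-identical genes, such as the histone, globin and Bcl2a1 copies, share reads, and their single values are uncertain.

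Pairing by replicate number was checked from the correlation of deviations from group means. In experiment 1 the same-number libraries correlated at 0.970, 0.914 and 0.552, above the limit of 0.1 set for pairing. Libraries of other numbers correlated at up to 0.672, above the third of these values, so meeting the limit does not by itself show pairing. A blocked value therefore stands beside results of experiment 1 where it changes them.

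The alternatives were RLE factors, library size alone, no filter on low counts, a filter of 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, the replicate block, the 2 groups compared alone, a limit of at least 2-fold on the called genes, a threshold of 0.01 for overlaps, and each library left out in turn. Alternatives added after seeing the data were experiment 1 counts minus 1, a removed trend over transcript length and GC content (splines with 4 degrees of freedom, fitted on genes of at least 2 log2 CPM), that removal with the block, and experiment 2 without its first Dox_DMSO and NoDox_Entinostat libraries.

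The fits were tested on simulated data of the same size with 200 genes changed. In experiment 1 they recovered 4.48% of genes changed 1.5-fold, 56.7% at 2-fold and 93.9% at 4-fold, with 6.36% of calls false. For entinostat without doxycycline they recovered 25.4% at 2-fold and 86.4% at 4-fold. For the interaction they recovered 4.48% at 2-fold and 57.6% at 4-fold, with 4.55% of calls false. The simulated libraries were drawn independently, without the length trend shared by some real libraries. The number of genes changed also differs from that in the real data. These rates of recovery and of false calls therefore need not hold for the real data.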

Results

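The series holds 18 libraries of polyadenylated RNA from a mouse erythroleukemic line, leukemic erythroid cells of Spi1-transgenic mice that overproduce the transcription factor SPI1 (PU.1). Doxycycline for 48 h switched on a short hairpin RNA against Spi1, and entinostat, an inhibitor of the class I histone deacetylases, was given at 3 µM for 6 h, with DMSO as its vehicle. Experiment 1 compared cells without doxycycline (Exp1_NoDox) and with it (Exp1_Dox). Experiment 2 crossed doxycycline with entinostat in 4 groups, named here NoDox_DMSO, Dox_DMSO, NoDox_Entinostat and Dox_Entinostat. Each of the 6 groups had 3 libraries.

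Library totals in experiment 1 were 82.7, 114 and 88.0 M counts without doxycycline and 96.1, 99.9 and 86.0 M with it. In experiment 2 they were 48.1, 47.3 and 48.8 M for NoDox_DMSO and 46.5, 48.8 and 48.9 M for Dox_DMSO. The entinostat libraries held 44.9, 46.7 and 47.3 M counts without doxycycline and 44.3, 43.1 and 44.4 M with it. Levels are means in CPM (counts per M counts of the library after TMM scaling) ± SD over 3 libraries, and log2 fold changes are given ± standard error, with 3 libraries in each group compared. No group carried a control hairpin, so an effect of doxycycline holds both the drug and the loss of Spi1 RNA.

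Spi1 itself (ENSMUSG00000002111, mm10 chromosome 2, 91082390 to 91115756), the target of the hairpin, was followed first. In experiment 1 its RNA stood at 379, 455 and 459 CPM without doxycycline and at 133, 125 and 132 CPM with it, a log2 fold change of -1.73 ± 0.10 (adjusted p = 0.000828). In DMSO it stood at 200, 259 and 251 CPM without doxycycline and at 59.5, 126 and 105 CPM with it, a log2 fold change of -1.29 ± 0.33 (adjusted p = 0.0264). In entinostat it fell from 221, 480 and 482 CPM to 98.5, 162 and 132 CPM, a log2 fold change of -1.59 ± 0.33 (adjusted p = 0.00722). Entinostat without doxycycline gave Spi1 a log2 fold change of 0.74 ± 0.33 (adjusted p = 0.0813), and entinostat with doxycycline 0.43 ± 0.33 (adjusted p = 0.260). The call in DMSO was lost without the first Dox_DMSO library (adjusted p = 0.0507), the third Dox_DMSO library (0.0688), the second NoDox_DMSO library (0.0900) or the third (0.0903). The entinostat value without doxycycline passed the test without the first NoDox_Entinostat library (1.02, adjusted p = 0.00853) or the first Dox_DMSO library (0.73, adjusted p = 0.0375).

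**Figure D1:**
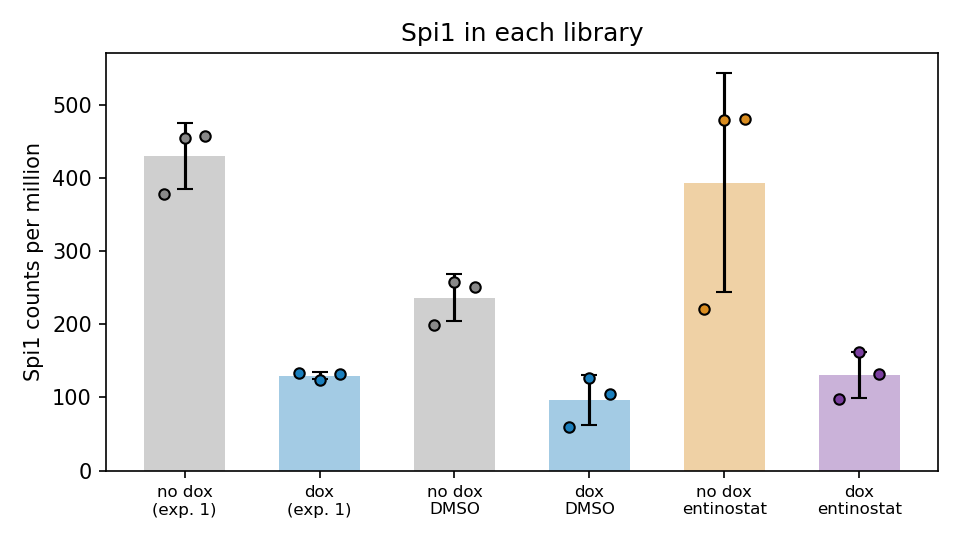
Spi1 RNA in CPM (y axis, linear) in the 6 groups (x axis); bars are group means, error bars the SD and points the 3 libraries of each group. The mean was 431 without and 130 with doxycycline in experiment 1, 237 and 96.9 in DMSO, and 394 and 131 in entinostat.

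The first comparison asked which genes respond when Spi1 RNA is lowered for 48 h. Among genes of at least 5 CPM in experiment 1, the largest rises were those of Ephb3, an ephrin receptor (log2 fold change 4.18 ± 0.26, from 0.988 ± 0.335 to 18.0 ± 1.34 CPM, adjusted p = 0.000882), and of the butyrophilin-like gene Btnl10 (3.88 ± 0.28, from 2.92 ± 1.12 to 43.2 ± 2.57 CPM, adjusted p = 0.00105). Pkhd1l1 rose by 3.11 ± 0.27, the formin gene Fhdc1 by 2.71 ± 0.24 and Epb42, a protein of the red cell membrane, by 2.64 ± 0.14. Plcb2, a phospholipase C, changed by -5.13 ± 0.47 (from 15.7 ± 5.99 to 0.451 ± 0.205 CPM, adjusted p = 0.00184) and Lcp2, an adaptor of immune receptors, by -3.97 ± 0.30 (from 61.9 ± 7.84 to 3.95 ± 1.45 CPM). The ribonuclease Rnase6 changed by -4.43 ± 0.29, Tmem176b by -4.38 ± 0.18, annexin Anxa2 by -3.64 ± 0.16 and galectin Lgals1 by -3.35 ± 0.14. Bcl2l11, which encodes the pro-apoptotic protein BIM, rose by 1.46 ± 0.17 (adjusted p = 0.00355).

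Of 27 fixed gene lists tested in experiment 1, 10 passed. Of 27 genes of the red cell membrane and surface, 14 rose and 1 fell (15 and 2 adjusted over the list alone; camera adjusted p = 1.80e-08, and 0.179 with an estimated correlation), among them dematin Dmtn (2.69 ± 0.14), aquaporin Aqp1 (1.74 ± 0.15) and tropomodulin Tmod1 (1.39 ± 0.13). Of 16 globin and heme synthesis genes, 9 rose and 0 fell (9 and 0 adjusted over the list alone; adjusted p = 3.05e-06, and 0.374 with an estimated correlation), including the heme enzymes Uros (1.85 ± 0.18) and Ppox (1.18 ± 0.09). Of 16 erythroid transcription factors, 6 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.00248, and 0.256 with an estimated correlation); Sox6 rose by 2.08 ± 0.14, Tal1 by 0.62 ± 0.06 and Klf3 by 0.56 ± 0.07. Of 46 S phase genes, 7 rose and 1 fell (7 and 2 adjusted over the list alone; adjusted p = 0.00104, and 0.179 with an estimated correlation), with cyclin Ccne1 up by 0.84 ± 0.09. Of 27 ATF4 and stress response genes, 3 rose and 1 fell (5 and 1 adjusted over the list alone; adjusted p = 0.000152, and 0.591 with an estimated correlation).

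Of 29 macrophage and myeloid genes known as SPI1 targets, 18 fell and 2 rose (22 and 2 adjusted over the list alone; adjusted p = 4.20e-11, and 0.179 with an estimated correlation). The actin-binding coronin Coro1a changed by -2.96 ± 0.17 (from 172 ± 25.2 to 22.1 ± 3.81 CPM), the leukocyte integrin Itgb2 by -2.13 ± 0.13 and the kinase Lyn by -0.99 ± 0.07. Of 12 stem and progenitor regulators, 6 fell and 0 rose (7 and 0 adjusted over the list alone; adjusted p = 0.00118, and 0.179 with an estimated correlation). Ikzf2 stood at -1.99 ± 0.19 and Hhex at -0.98 ± 0.09. Glycolysis genes fell in 8 of 19 cases and rose in 0 (10 and 1 adjusted over the list alone; adjusted p = 1.07e-05, and 0.196 with an estimated correlation), such as Aldoc (-1.44 ± 0.16) and Pgam1 (-0.85 ± 0.09). ETS family factors fell in 7 of 15 cases and rose in 0 (9 and 0 adjusted over the list alone; adjusted p = 0.000109, and 0.256 with an estimated correlation), such as Etv4 (-1.45 ± 0.18) and Elf1 (-0.89 ± 0.10). Mast cell and basophil genes fell in 3 of 6 cases and rose in 0 (3 and 0 adjusted over the list alone; adjusted p = 0.0109, and 0.196 with an estimated correlation). None of the 10 passed with an estimated correlation. Interferon-stimulated genes rose in 2 and fell in 4 of 31 cases (adjusted p = 0.174), and that list passed downwards with the pairs as a block (0.0492).

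Together 727 genes rose and 1154 fell in experiment 1, of 13811 tested, and 275 of the rises and 542 of the falls were at least 2-fold. The groups did not overlap in 32.1% of all genes tested, where chance gives 10% for 3 against 3. Same-number libraries met the limit for pairing in this experiment, and with the replicate number as a block 3611 genes rose and 3416 fell. Without the third Exp1_NoDox library 684 genes passed, without the third Exp1_Dox library 894 and without the second Exp1_Dox library 1052.

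In the DMSO arm of experiment 2, Btnl10 rose by 4.97 ± 0.38 (to 47.0 ± 21.8 CPM, adjusted p = 3.82e-06) and Ephb3 by 4.81 ± 0.49 (from 0.902 ± 0.202 to 25.4 ± 13.5 CPM, adjusted p = 4.07e-05). Slc4a1, the anion exchanger of the red cell membrane, rose by 4.19 ± 0.63, Pkhd1l1 by 3.79 ± 0.25 and Bcl2l11 by 1.70 ± 0.21. Lcp2 changed by -5.66 ± 0.29 (from 59.8 ± 8.86 to 1.18 ± 0.268 CPM, adjusted p = 4.86e-07), Plcb2 by -5.52 ± 0.43, Rnase6 by -5.37 ± 0.38, Ccdc88b by -5.04 ± 0.35 and Lgals1 by -4.55 ± 0.35 (from 77.0 to 3.30 ± 1.62 CPM). This comparison asked the same question as experiment 1 in libraries of their own. Of 15051 genes tested, 568 rose and 833 fell, 381 and 593 of them at least 2-fold, and without the first Dox_DMSO and NoDox_Entinostat libraries 2697 rose and 2149 fell. The groups did not overlap in 25.8% of genes tested, against 10% by chance. Without the third NoDox_DMSO library 862 genes passed, without the second NoDox_DMSO library 908 and without the second Dox_DMSO library 928.

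Red cell membrane and surface genes rose in 14 of 27 cases and fell in 1 (19 and 1 adjusted over the list alone; adjusted p = 3.76e-13, and 0.150 with an estimated correlation), among them aquaporin Aqp1 (2.44 ± 0.28) and the blood group genes Rhd (1.91 ± 0.20) and Kel (1.79 ± 0.16). Globin and heme synthesis genes rose in 8 of 16 cases and fell in 0 (11 and 0 adjusted over the list alone; adjusted p = 3.70e-09, and 0.0621 with an estimated correlation), including Uros (1.82) and the mitochondrial iron importer Slc25a37 (1.39 ± 0.21). Myeloid genes known as SPI1 targets fell in 20 of 34 cases and rose in 1 (23 and 2 adjusted over the list alone; adjusted p = 7.33e-14, and 0.0621 with an estimated correlation). Coro1a stood at -3.79 ± 0.28, the adaptor Dok2 at -3.29 ± 0.27 and Itgb2 at -2.97 ± 0.29. Glycolysis genes fell in 6 of 19 cases and rose in 0 (9 and 0 adjusted over the list alone; adjusted p = 2.88e-06, and 0.441 with an estimated correlation). Mast cell and basophil genes fell in 6 of 9 cases and rose in 0 (8 and 0 adjusted over the list alone; adjusted p = 5.87e-06, and 0.0275 with an estimated correlation). Granzyme Gzmb stood at -4.12 ± 0.56. Of these 5 lists, the mast cell list alone passed with an estimated correlation.

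Another 3 lists passed in DMSO with weaker values. Stem and progenitor regulators fell in 4 of 13 cases and rose in 0 (7 and 0 adjusted over the list alone; adjusted p = 0.00252, and 0.597 with an estimated correlation), with Ikzf2 at -1.74 ± 0.21. ETS family factors fell in 4 of 16 cases and rose in 0 (5 and 0 adjusted over the list alone; adjusted p = 0.00277, and 0.888 with an estimated correlation). Erythroid transcription factors rose in 2 of 16 cases and fell in 0 (3 and 1 adjusted over the list alone; adjusted p = 0.0422, and 0.888 with an estimated correlation), with Sox6 up by 2.58 ± 0.36. Without the first Dox_DMSO library the stem list had an adjusted p of 0.0594 and the ETS list 0.173, and without that and the first NoDox_Entinostat library 0.0815 and 0.139. The erythroid factor list lost its call without the second (0.241) or the third Dox_DMSO library (0.208), the first (0.0598) or second Dox_Entinostat library (0.0553) or the first NoDox_DMSO library (0.0805), and with library size alone (0.0592) or a filter of 1 CPM in at least 3 libraries (0.0501).

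Set side by side, 996 of the 1845 genes called in experiment 1 and tested in both (54.0%) were called with the same sign in DMSO, and 0 with the opposite sign. Genes up in both numbered 383 where 29.9 were expected (Fisher's exact test, odds ratio 93.1, 95% interval 74.4 to 116), and genes down in both 613 where 68.5 were expected (odds ratio 88.1, 71.9 to 108). The genes up in both numbered 173 without the third Exp1_NoDox library (odds ratio 241), 239 without the third Exp1_Dox library (138), 252 without the first NoDox_DMSO library (117) and 614 without the first Dox_DMSO and NoDox_Entinostat libraries (29.4). They numbered 590 with DESeq2 (58.2), 603 with the length and GC trend removed (51.3), 149 at a threshold of 0.01 (145) and 223 at a change of at least 2-fold in both (478). Across genes, which are not independent replicates, the fold changes correlated with Pearson's r of 0.905 and Spearman's rho of 0.810. With experiment 1 paired as a block and the block in both fits, 26.8% of its larger set of calls were shared, with 789 genes up in both (odds ratio 56.8). Without the third Exp1_NoDox library the share was 82.7%, of a smaller set of calls.

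**Figure D2:**
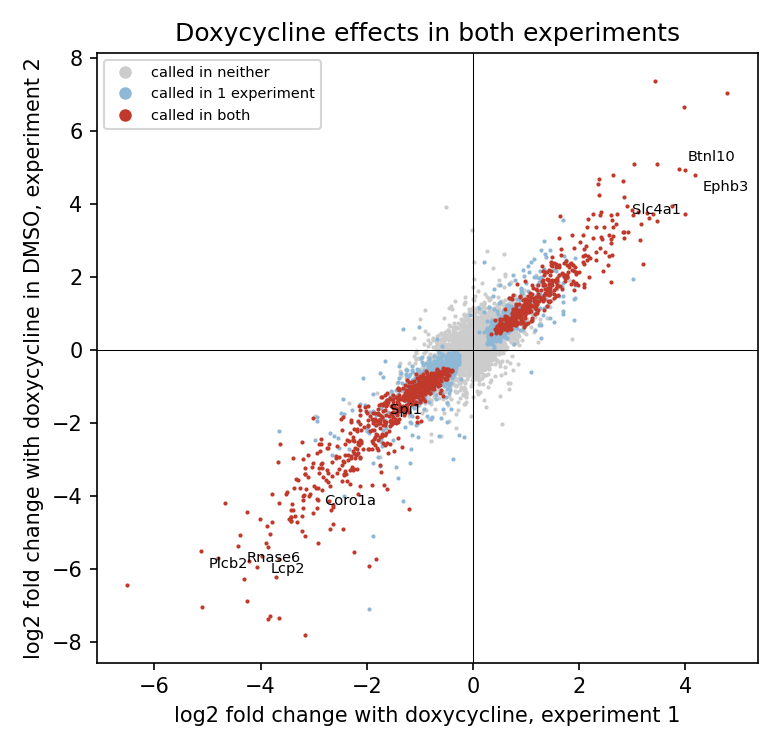
Log2 fold change with doxycycline in experiment 1 (x axis) against that in the DMSO arm of experiment 2 (y axis), one point per gene tested in both. Grey points were called in neither, blue in 1 experiment and red in both; Ephb3 and Btnl10 lie at the upper right, at 4.18 and 3.88 on the x axis, and Plcb2 and Lcp2 at the lower left, at -5.13 and -3.97.

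The title of the series asks about HDAC1 and the Polycomb complex PRC2, so their own RNA was followed. The deacetylase genes Hdac1 (-0.02 ± 0.07), Hdac2 (-0.07) and Hdac3 (-0.02) did not pass the test with doxycycline in experiment 1, and neither did the PRC2 genes Ezh2 (0.24 ± 0.13, adjusted p = 0.312), Suz12 (0.25 ± 0.10, adjusted p = 0.193), Eed (-0.04) and Ezh1 (-0.02). Hdac1 stood at 75.4 CPM in Exp1_NoDox and at 338 CPM in NoDox_DMSO, and the counter and annotation of the tables are not stated. With the pairs as a block, Ezh2 (adjusted p = 0.000331) and Suz12 (0.000211) passed. Of 11 PRC2 subunit genes 0 rose and 0 fell by edgeR in either experiment (adjusted p of the list 0.935 and 0.759). At an unadjusted p under 0.05, 1 gene passed in experiment 1 and 0 in DMSO, and DESeq2 called 1 (Mtf2) and 0 and limma-voom 0 and 0. HDAC and corepressor subunits rose in 3 and fell in 4 of 34 cases in experiment 1 (adjusted p = 0.963) and rose in 1 and fell in 2 in DMSO (0.990). HOX and developmental regulators known as PRC2 targets rose in 3 and fell in 1 of 16 cases in experiment 1 (5 and 2 adjusted over the list alone; adjusted p = 0.197), and rose in 4 and fell in 1 of 21 in DMSO (4 and 1 adjusted over the list alone; adjusted p = 0.0567). Foxc1 and Hoxd8 rose and Pax6 fell in both. The HOX list passed in experiment 1 without the second Exp1_Dox library (0.0319). In DMSO it passed, with adjusted p values from 0.0202 to 0.0424, when any library was left out other than the second or the third Dox_DMSO, the third Dox_Entinostat or the first NoDox_Entinostat library. The erythroid regulators Gata1 (0.13 ± 0.07, adjusted p = 0.326) and Klf1 (0.22 ± 0.09, adjusted p = 0.199) did not pass in experiment 1, and both passed with the pairs as a block (0.0101 and 0.00186).

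The entinostat comparison without doxycycline asked which genes respond to deacetylase inhibition while SPI1 is high. Genes barely detected in DMSO were among those that rose furthest. Ehf, an epithelial ETS factor, rose by 7.78 ± 0.45 (from 0.169 ± 0.0147 to 37.6 ± 10.8 CPM, adjusted p = 2.01e-07) and Mgarp, a mitochondrial protein gene, by 6.30 ± 0.30 (from 0.543 ± 0.0412 to 42.9 ± 10.5 CPM, adjusted p = 6.16e-08). The receptor kinase gene Erbb3 rose by 7.23 ± 0.56, the potassium channel Kcnj10 by 7.13 ± 0.57 and the complement inhibitor Cd59a by 6.41 ± 0.40. The largest falls were smaller. C2cd4a changed by -4.38 ± 0.30 (from 21.2 ± 2.39 to 1.01 ± 0.202 CPM), the tRNA methyltransferase Trmt61a by -2.59 ± 0.25, the repressor Bend3 by -2.54 ± 0.32 and the folate carrier Slc19a1 by -2.25 ± 0.19 (from 95.3 ± 8.76 to 20.1 ± 2.68 CPM).

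Bcl2l11 rose by 1.92 ± 0.21 (from 8.98 ± 0.687 to 34.1 ± 8.15 CPM, adjusted p = 1.88e-05) and the cell cycle inhibitor Cdkn1a by 2.76 ± 0.38 (from 5.64 ± 1.43 to 38.2 ± 12.6 CPM, adjusted p = 8.34e-05). Myc changed by -1.58 ± 0.26 (adjusted p = 0.000321), Klf1 by -1.33 ± 0.23 (0.000447) and Gata1 by -0.92 ± 0.18 (0.00124). Ezh1 rose by 1.13 ± 0.25 (adjusted p = 0.00263), whereas Ezh2 (-0.17), Suz12 (-0.31), Eed (-0.07) and Hdac1 (0.07) did not pass. In all 4554 genes rose and 2545 fell, 3804 and 743 of them at least 2-fold, and the groups did not overlap in 60.2% of genes tested, against 10% by chance. The split of calls depended on the scaling. With library size alone 5417 rose and 1233 fell, and the median log2 fold change of all genes was 0.32 in place of 0.07.

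Of 29 lists tested for entinostat without doxycycline, 11 rose and 6 fell. The filter keeps a gene expressed in a single group, so genes silent in DMSO can enter through the entinostat libraries alone. Such genes can only rise with entinostat, which favours rises in lists of mostly silent genes. Replication-dependent histone genes rose in 18 of 20 cases and fell in 0 (18 and 0 adjusted over the list alone; adjusted p = 3.02e-06, and 0.295 with an estimated correlation), with H1f3 up by 4.97 ± 0.32 (to 62.8 ± 9.40 CPM). Such transcripts mostly lack a polyA tail, whereas the libraries were made from polyadenylated RNA, and their gene copies share sequence. Genes known to rise with HDAC inhibitors rose in 17 of 23 cases and fell in 1 (18 and 1 adjusted over the list alone; adjusted p = 0.000116, and 0.384 with an estimated correlation), including the linker histone H1f0 (2.48 ± 0.19, from 66.2 to 369 CPM) and tubulin Tubb3 (4.68 ± 0.42). Neuronal genes known as REST targets rose in 7 of 7 cases (7 and 0 adjusted over the list alone; adjusted p = 0.000654, and 0.295 with an estimated correlation), such as the synaptotagmin Syt11 (4.74 ± 0.44). HOX and developmental regulators known as PRC2 targets rose in 14 of 21 cases and fell in 3 (14 and 3 adjusted over the list alone; adjusted p = 0.00494, and 0.247 with an estimated correlation). Neurog2 stood at 4.45 ± 0.36, Hoxc6 at 2.86 ± 0.37, Pax9 at 2.68 ± 0.25 and Lhx2 at 2.39 ± 0.24; with a filter of 1 CPM in at least 3 libraries this list had an adjusted p of 0.110. Cell cycle inhibitors rose in 9 of 17 cases and fell in 0 (12 and 0 adjusted over the list alone; adjusted p = 0.00675, and 0.247 with an estimated correlation). Cyclin Ccng2 stood at 2.62 ± 0.20.

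Another 6 of the lists that rose follow. Myeloid genes known as SPI1 targets rose in 20 of 34 cases and fell in 2 (20 and 2 adjusted over the list alone; adjusted p = 0.000834, and 0.295 with an estimated correlation), such as the tetraspanin Cd53 (4.08 ± 0.39) and the receptor Pirb (4.13 ± 0.50). Mast cell and basophil genes rose in 8 of 9 cases and fell in 0 (9 and 0 adjusted over the list alone; adjusted p = 0.00043, and 0.0633 with an estimated correlation); the IL-33 receptor gene Il1rl1 rose by 1.72 ± 0.17 (from 369 to 1218 CPM). Chemokines and cytokines rose in 15 of 18 cases and fell in 2 (15 and 2 adjusted over the list alone; adjusted p = 0.000402, and 0.0633 with an estimated correlation). Cxcl10 stood at 3.75 ± 0.40 and Il1b at 3.44 ± 0.43. Interferon-stimulated genes rose in 17 of 31 cases and fell in 2 (17 and 3 adjusted over the list alone; adjusted p = 0.00556, and 0.433 with an estimated correlation). Ifit2 stood at 2.90 ± 0.29. Stromal and endothelial genes rose in 6 of 6 cases (6 and 0 adjusted over the list alone; adjusted p = 0.00478, and 0.178 with an estimated correlation). In experiment 1, without entinostat, 2 genes of this list passed the filter. Collagen Col1a1 stood at 4.29 ± 0.50. T and NK cell genes rose in 4 of 5 cases and fell in 0 (4 and 0 adjusted over the list alone; adjusted p = 0.0127, and 0.188 with an estimated correlation). Cd247 stood at 3.23 ± 0.31.

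The 6 lists that fell follow. S phase genes fell in 24 of 46 cases and rose in 0 (24 and 0 adjusted over the list alone; adjusted p = 9.51e-07, and 0.247 with an estimated correlation). Ccne1 stood at -1.27 ± 0.13 and Dtl at -1.12 ± 0.16. Cholesterol synthesis genes fell in 12 of 22 cases and rose in 0 (12 and 0 adjusted over the list alone; adjusted p = 5.28e-06, and 0.238 with an estimated correlation). Squalene epoxidase Sqle stood at -1.57 ± 0.25. ATF4 and stress response genes fell in 11 of 27 cases and rose in 1 (11 and 1 adjusted over the list alone; adjusted p = 0.000654, and 0.452 with an estimated correlation). Ddit3 stood at -1.68 ± 0.29. G2 and mitosis genes fell in 14 of 55 cases and rose in 2 (7 and 1 adjusted over the list alone; adjusted p = 0.00135, and 0.452 with an estimated correlation). Cdc20 stood at -1.14 ± 0.19. Erythroid transcription factors fell in 8 of 16 cases and rose in 1 (8 and 1 adjusted over the list alone; adjusted p = 0.00478, and 0.544 with an estimated correlation). Bcl11a stood at -1.61 ± 0.23, Lmo2 at -1.57 ± 0.16 and Tal1 at -1.12 ± 0.17; without the first Dox_DMSO and NoDox_Entinostat libraries the adjusted p of this list was 0.104. HDAC and corepressor subunits fell in 10 of 34 cases and rose in 3 (9 and 3 adjusted over the list alone; adjusted p = 0.00478, and 0.544 with an estimated correlation). Mbd3 stood at -1.35 ± 0.20; the adjusted p of this list was 0.0506 without the first NoDox_Entinostat library and 0.0639 without that and the first Dox_DMSO library. None of the 17 lists passed with an estimated correlation.

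Another 14 lists did not pass or had too few members for the test. Globin and heme synthesis genes rose in 7 and fell in 4 of 16 cases (adjusted p = 0.701) and red cell membrane genes rose in 8 and fell in 5 of 27 (0.698), although Alas2, the first enzyme of heme synthesis, rose by 1.91 ± 0.33. Stem and progenitor regulators rose in 5 and fell in 4 of 13 cases (0.919), with Ikzf2 at 2.98 ± 0.21 and Gata2 at -1.48 ± 0.24. Megakaryocyte and platelet genes rose in 9 and fell in 2 of 17 cases (0.133), p53 target genes rose in 9 and fell in 3 of 25 (0.272), and BCL2 family genes rose in 7 and fell in 5 of 18 (0.993). Immediate early genes rose in 14 and fell in 2 of 21 cases (0.0670) and passed without the first NoDox_Entinostat library (0.0153). EPO and STAT5 response genes rose in 5 and fell in 7 of 17 cases (0.105), with the erythropoietin receptor Epor at -1.55 ± 0.13, and passed without the first NoDox_DMSO library (0.0399) or the third NoDox_Entinostat library (0.0488). PRC2 subunits rose in 1 and fell in 1 of 11 cases (0.137), glycolysis genes rose in 3 and fell in 3 of 19 (0.164), ETS family factors rose in 3 and fell in 2 of 16 (0.898), and of 11 mitochondrially encoded genes 0 were called by edgeR, DESeq2 or limma-voom (0.698), with 0 at an unadjusted p under 0.05. Neutrophil granule genes rose in 3 of 4 cases and B cell genes in 4 of 4, too few members for the list test. In experiment 1, without entinostat, 2 neutrophil granule genes and 1 B cell gene passed the filter.

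**Figure D3:**
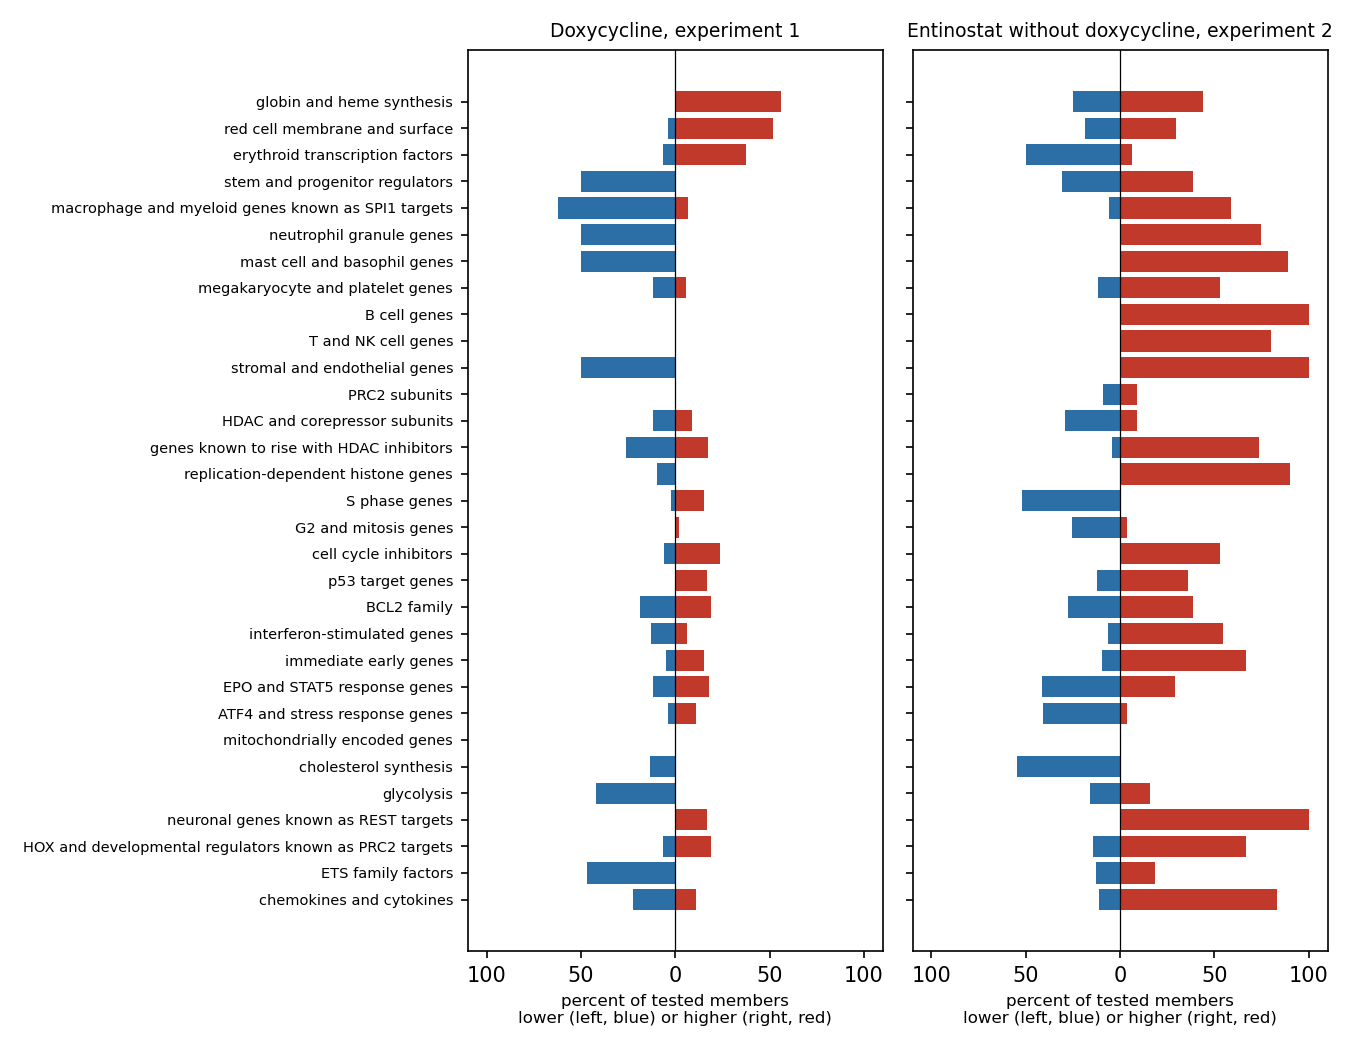
Percent of tested members of each of the 31 gene lists called lower (blue, to the left) and higher (red, to the right), with doxycycline in experiment 1 (left panel) and with entinostat without doxycycline (right panel). Of the myeloid SPI1 targets 18 of 29 fell with doxycycline, and 20 of 34 rose with entinostat. Members silent in DMSO can enter the right panel through the entinostat libraries alone.

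With doxycycline present, entinostat raised Mgarp by 7.66 ± 0.32 (from 0.349 ± 0.0809 to 70.8 ± 21.3 CPM, adjusted p = 3.88e-08), the sialic acid hydroxylase gene Cmah by 7.01 ± 0.37 and the lectin receptor Clec4e by 6.87 ± 0.44. C2cd4a changed by -4.51 ± 0.30, Bend3 by -3.71 ± 0.34, Myc by -2.40 ± 0.27 and Klf1 by -2.26 ± 0.24. This comparison asked what deacetylase inhibition does once Spi1 RNA is low. In all 5097 genes rose and 4498 fell, 4321 and 2290 of them at least 2-fold. With a filter of 1 CPM in at least 3 libraries 3861 rose and 3971 fell, and with library size alone 5770 rose and 3712 fell. The groups did not overlap in 66.0% of genes tested, against 10% by chance. With and without doxycycline, 3863 genes rose in both entinostat comparisons where 1542 were expected and 2255 fell in both where 761 were expected. Long transcripts were low in the Dox_Entinostat libraries, and the fold changes of this comparison had a slope of -0.32 on log2 transcript length, against -0.01 for entinostat without doxycycline.

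Several genes of PRC2 fell in this comparison, in which 4498 of 15051 genes fell and the slope on log2 transcript length was -0.32. A length bias of the libraries cannot be told apart from the combined treatment here. In entinostat without doxycycline, with a slope of -0.01, 2 of 11 PRC2 genes and 13 of 34 HDAC and corepressor genes were called in either direction. That slope joins NoDox_Entinostat libraries with opposite slopes (-0.28, 0.17 and 0.15 against the NoDox_DMSO mean). Its calls therefore do not show the result without a length bias. With doxycycline present, Suz12 changed by -0.87 ± 0.25 (adjusted p = 0.00822), Phf19 by -1.36 ± 0.16, Aebp2 by -1.74 ± 0.31, and 6 of 11 PRC2 subunit genes fell, 0 rose, with the list at adjusted p = 0.162. HDAC and corepressor subunits fell in 24 of 34 cases and rose in 2 (25 and 2 adjusted over the list alone; adjusted p = 0.000147, and 0.502 with an estimated correlation), with Sin3a at -2.04, Mbd3 at -1.74 and Hdac2 at -0.72 ± 0.17. Erythroid transcription factors fell in 14 of 16 cases and rose in 0 (14 and 0 adjusted over the list alone; adjusted p = 0.000117, and 0.502 with an estimated correlation), and red cell membrane genes fell in 13 of 27 and rose in 3 (13 and 3 adjusted over the list alone; adjusted p = 0.00932, and 0.515 with an estimated correlation). S phase genes fell in 32 of 46 cases and rose in 2 (32 and 2 adjusted over the list alone; adjusted p = 4.45e-06, and 0.414 with an estimated correlation), ATF4 and stress response genes fell in 22 of 27 and rose in 1 (24 and 1 adjusted over the list alone; adjusted p = 4.45e-06, and 0.414 with an estimated correlation), and cholesterol synthesis genes fell in 17 of 22 and rose in 0 (18 and 0 adjusted over the list alone; adjusted p = 9.15e-06, and 0.295 with an estimated correlation). Histone genes rose in 19 of 20 cases and fell in 0 (19 and 0 adjusted over the list alone; adjusted p = 4.45e-06, and 0.414 with an estimated correlation), and mast cell genes in 9 of 9 (9 and 0 adjusted over the list alone; adjusted p = 0.00413, and 0.162 with an estimated correlation). None of the 17 lists past the test here, 8 up and 9 down, passed with an estimated correlation.

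The study's question of shared repression was put as the overlap between genes that rose when Spi1 RNA fell and genes that rose with entinostat. Among the genes that did both, Ephb3 rose by 4.18 with doxycycline and by 3.83 ± 0.48 with entinostat, the butyrophilin Btn1a1 by 1.53 ± 0.12 and 3.57 ± 0.28, the retinal dehydrogenase Aldh1a1 by 2.32 ± 0.31 and 2.41 ± 0.22, Nrip3 by 1.06 ± 0.13 and 3.59 ± 0.21, and Arhgap29 by 1.19 ± 0.13 and 3.11 ± 0.25. Of 715 genes up in experiment 1 and tested in both, 341 rose with entinostat without doxycycline where 162 were expected (Fisher's exact test, odds ratio 3.39, 95% interval 2.90 to 3.96, p = 6.49e-52), and 78 fell where 142 were expected. Genes down in experiment 1 rose with entinostat in excess as well, 429 where 256 were expected (odds ratio 2.28). Fisher's test takes genes as independent, which they are not, so its p and intervals overstate the certainty. As a set, the genes up in experiment 1 had a camera adjusted p of 0.000531 here, and 0.516 with an estimated correlation. With the replicate block in both fits the first overlap was 828 where 896 were expected (odds ratio 0.867), from a larger set of 3525 genes up in experiment 1. Without the second Exp1_Dox library 213 genes were shared (odds ratio 5.18), without the third Exp1_Dox library 192 (5.58), without the third Exp1_NoDox library 129 (6.47), and at a change of at least 2-fold in both 198 where 45.6 were expected (14.8).

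The 341 shared genes were also followed with doxycycline present. Their median log2 fold change was 0.90 with doxycycline and 1.77 without, 204 of them rose and 8 fell with doxycycline, and the interaction was below 0 in 313. These genes were chosen by their entinostat effect without doxycycline, which lowers the interaction by itself. Arhgap29 rose by 2.07 with doxycycline present, Btn1a1 by 1.83 and Aldh1a1 by 1.26, whereas Ephb3 stood at 0.29 (adjusted p = 0.547).

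In entinostat-treated cells, doxycycline raised the red cell microRNA gene Mir144 by 7.27 ± 0.58 and Slc4a1 by 3.26 ± 0.59. The myosin Myo1g changed by -5.45 ± 0.41, the tetraspanin Cd53 by -4.88 ± 0.41, Dock2 by -4.58 ± 0.39 and Lcp2 by -4.26 ± 0.27. This comparison asked what loss of Spi1 RNA does once deacetylases are inhibited. Globin and heme synthesis genes rose in 11 of 16 cases and fell in 0 (11 and 0 adjusted over the list alone; adjusted p = 3.55e-06, and 0.168 with an estimated correlation). Uros stood at 2.19 ± 0.30. Myeloid genes known as SPI1 targets fell in 25 of 34 cases and rose in 1 (27 and 1 adjusted over the list alone; adjusted p = 6.61e-13, and 0.0887 with an estimated correlation). Glycolysis genes fell in 16 of 19 cases and rose in 0 (17 and 0 adjusted over the list alone; adjusted p = 7.73e-07, and 0.423 with an estimated correlation). Slc2a3 stood at -1.74 and Slc2a1 at -1.59, both glucose transporters, and Aldoc at -1.67 ± 0.22. ETS family factors fell in 12 of 16 cases and rose in 0 (13 and 0 adjusted over the list alone; adjusted p = 0.000169, and 0.764 with an estimated correlation). Etv4 stood at -2.17 and Etv5 at -2.16 ± 0.30. Bcl2l11 did not pass here (0.55 ± 0.21, adjusted p = 0.0682), and passed without the first Dox_DMSO library (0.0375).

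In all 1348 genes rose and 2266 fell with doxycycline in entinostat, 879 and 1142 of them at least 2-fold, and with library size alone 1107 rose and 3149 fell. Among changes of at least 2-fold, rises outnumbered falls with DESeq2 (1168 and 1125), with limma-voom (1157 and 1106), without the first NoDox_Entinostat library (2134 and 2074) and without that and the first Dox_DMSO library (2309 and 2136). The groups did not overlap in 37.6% of genes tested, against 10% by chance. Of the genes called in experiment 1, 1004 were called with the same sign here and 10 with the opposite sign. The count of calls depended on single libraries. It was 7583 without the first NoDox_Entinostat library and 5711 without the first Dox_DMSO library, and 1521, 1107, 1080 and 994 without the second or the third Dox_Entinostat or the second or the third NoDox_Entinostat library. The fold changes had a slope of -0.28 on log2 transcript length.

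The interaction asked whether the effect of doxycycline differed between entinostat and DMSO. Lgals1 (ENSMUSG00000068220, mm10 chromosome 15, 78926725 to 78930465) changed by -4.55 with doxycycline in DMSO and by -1.06 in entinostat, an interaction of 3.49 ± 0.43 (adjusted p = 0.00493). Tespa1, an adaptor of lymphocyte signalling, changed by -5.79 in DMSO and by -1.66 in entinostat (interaction 4.14 ± 0.47, adjusted p = 0.00493). The lipid phosphatase Plpp1 rose by 3.24 in DMSO and had a value of 0.67 in entinostat (interaction -2.57 ± 0.32, adjusted p = 0.00493). These 3 passed whichever library was left out. In all 41 genes passed, 25 with a positive and 16 with a negative interaction, and in 41 of 41 the doxycycline effect was smaller in entinostat. Negative interactions outnumbered positive ones without a filter (139 and 67), without the first Dox_DMSO library (1619 and 1018), without the first NoDox_Entinostat library (2133 and 928) and without both (4646 and 3326).

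The 16 genes with a negative interaction had all risen in experiment 1, and 24 of the 25 with a positive one had fallen there. Ephb3 had a doxycycline effect of 4.81 in DMSO against 1.27 in entinostat (interaction -3.54 ± 0.61, adjusted p = 0.0350) and Btnl10 by 4.97 against 1.56 (-3.40 ± 0.47, adjusted p = 0.00953). Ephb3 kept its call only without the first Dox_DMSO or the first NoDox_Entinostat library, with adjusted p values from 0.0852 to 0.143 without any other, and Btnl10 lost its call without the second Dox_Entinostat library (0.0540). The genes up in experiment 1 had a median interaction of -0.61 against -0.06 for all others (camera adjusted p = 1.47e-19, and 0.0285 with an estimated correlation). Red cell membrane genes lay lower as a list (median -0.93, adjusted p = 9.50e-05, and 0.791 with an estimated correlation), with 1 of 27 members called (5 adjusted over the list alone). HOX and developmental regulators known as PRC2 targets also lay lower (median -0.76, adjusted p = 0.00724, and 0.791 with an estimated correlation) with 0 of 21 members called by edgeR (2 adjusted over the list alone, 5 at an unadjusted p under 0.05, and 1, Foxc1, by DESeq2). The fold changes of this contrast had a slope of -0.31 on log2 transcript length, and the HOX list had an adjusted p of 0.104 with the length and GC trend removed and 0.124 without the first Dox_DMSO and NoDox_Entinostat libraries.

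The number of genes called in the interaction rested on single libraries. It was 3061 without the first NoDox_Entinostat library and 2637 without the first Dox_DMSO library. It was 20 without the second or 17 without the third Dox_DMSO library, 9 without the second or 20 without the third Dox_Entinostat library, 17 or 20 without the second or the third NoDox_DMSO library, and 18 without the second or the third NoDox_Entinostat library.

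**Figure D4:**
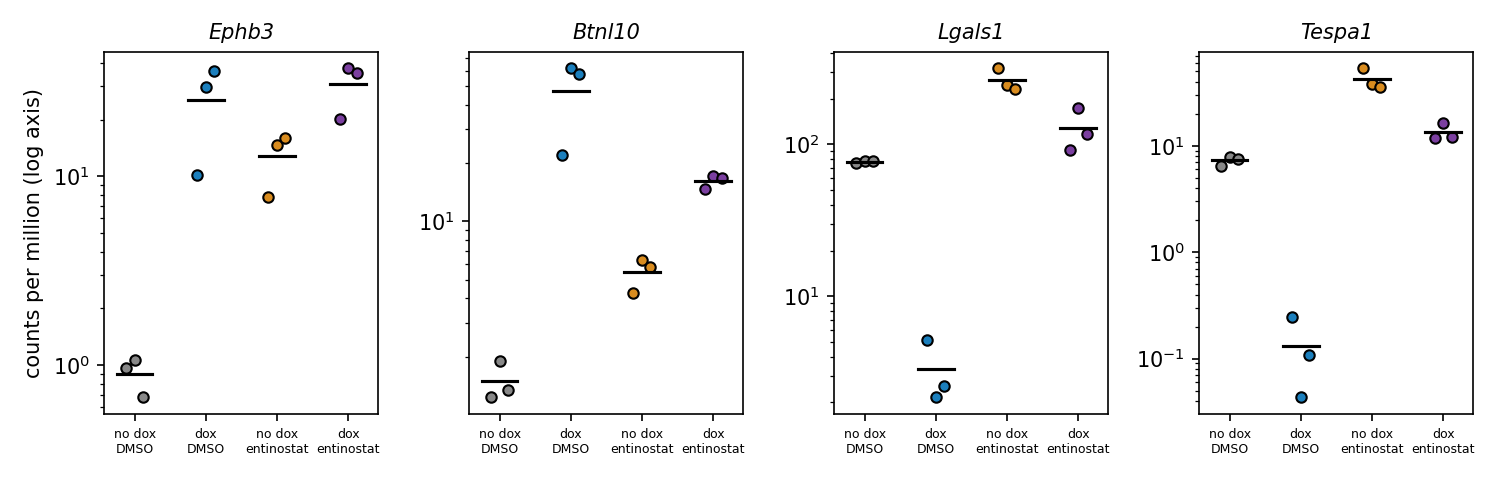
CPM on a log axis (y axis) of Ephb3, Btnl10, Lgals1 and Tespa1 in the 4 groups of experiment 2 (x axis); points are libraries and lines group means. Doxycycline raised Btnl10 by 4.97 in DMSO against 1.56 in entinostat on the log2 scale, and changed Lgals1 by -4.55 against -1.06.

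The first Dox_DMSO and the first NoDox_Entinostat library stood apart from the other libraries of their groups by transcript length. Against the NoDox_DMSO mean, the slope of log2 CPM on log2 transcript length was -0.23 in the first Dox_DMSO library and 0.18 and 0.19 in the others of that group. It was -0.28, 0.17 and 0.15 in the NoDox_Entinostat libraries, -0.29, -0.22 and -0.28 in the Dox_Entinostat libraries, and -0.07, 0.07 and 0.00 in the NoDox_DMSO libraries. Ribosomal protein genes took 15.2% of counts in the first Dox_DMSO library, 17.2% in the first NoDox_Entinostat library and 17.9, 22.7 and 19.0% in the Dox_Entinostat libraries, against 7.30 to 10.9% in the other libraries of experiment 2.

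**Figure D5:**
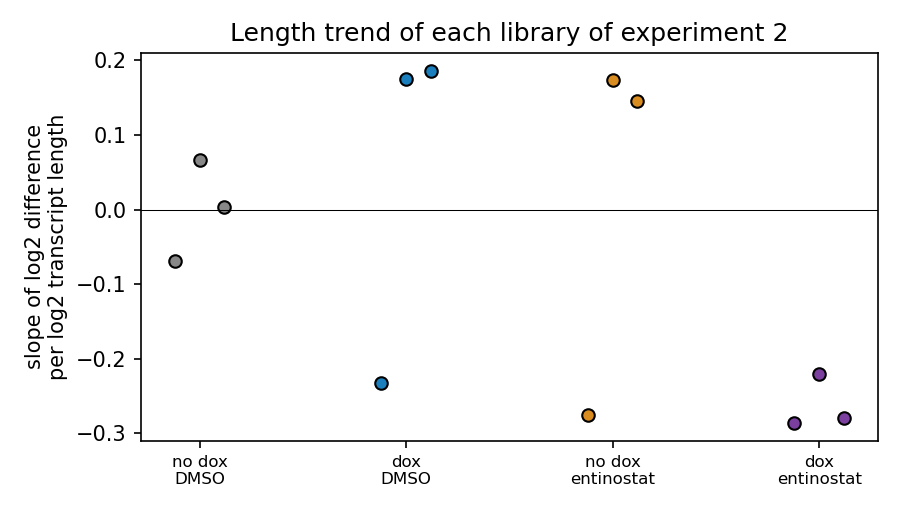
Slope of log2 CPM on log2 transcript length against the NoDox_DMSO mean (y axis) for each library of the 4 groups of experiment 2 (x axis). The first Dox_DMSO library (-0.23) and the first NoDox_Entinostat library (-0.28) lie with the Dox_Entinostat libraries (-0.29, -0.22 and -0.28).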

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

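The mean slope of the Dox_Entinostat libraries on transcript length and the label-swap positions with the length trend removed were tests chosen only after the result was seen, and so was the removal of a length and GC trend.

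The effect of doxycycline differed between entinostat and DMSO, as tested by the interaction, for 41 genes. Positive interactions were 4.14 for Tespa1, 3.49 for Lgals1, 3.16 for Rnase6, 3.13 for Scin and 3.02 for Cd200r1. Negative ones were -3.87 for Rnf212, -3.54 for Ephb3, -3.40 for Btnl10, -3.08 for Fhdc1, -2.57 for Plpp1, -1.76 for Pkhd1l1 and -1.58 for Rhd. Tespa1, Lgals1 and Plpp1 kept their calls whichever library was left out. Without the second Dox_Entinostat library, Scin, Cd200r1 and Btnl10 each had an adjusted p of 0.0540, Rnase6 0.0588 and Rnf212 0.0576. Rnase6 was also lost without the third Dox_DMSO library (0.0585) and Rnf212 without the second NoDox_DMSO library (0.0773). Ephb3, Fhdc1 and Rhd kept their calls without the first Dox_DMSO or first NoDox_Entinostat library and lost them without any of the other 10, with adjusted p values from 0.0503 to 0.157. Pkhd1l1 kept its call in the same cases and without the first NoDox_DMSO library, and lost it without any of the other 9 (0.0588 to 0.157).

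Among lists, the interaction was lower for red cell membrane genes (adjusted p = 9.50e-05), ATF4 and stress response genes (0.00288), HOX and developmental PRC2 targets (0.00724), erythroid transcription factors (0.00728) and HDAC and corepressor subunits (0.0133). None of these 5 passed with an estimated correlation (adjusted p = 0.791 for each), and the ATF4 list lost its call without the second Dox_Entinostat library (0.0633). With the length and GC trend removed, the HDAC list had 0.318 and the erythroid factor and HOX lists 0.104 each. With a filter of 1 CPM the HDAC and HOX lists had 0.0521 each, and the HOX list had 0.124 without the first Dox_DMSO and NoDox_Entinostat libraries. The genes up in experiment 1 had lower interactions (adjusted p = 1.47e-19, and 0.0285 with an estimated correlation) and those down in experiment 1 higher ones (2.73e-06). The latter call was lost with an estimated correlation (adjusted p = 0.150) and without the first Dox_DMSO and NoDox_Entinostat libraries (0.301).

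Long transcripts were low in the first Dox_DMSO and first NoDox_Entinostat libraries and in all Dox_Entinostat libraries. A length and GC trend alone is argued against for the first 2: removing it took out 44.6% and 46.3% of their variance, and their deviations from the group means still correlated at 0.924 (0.956 before). For a swap of labels, on a scale from DMSO at 0 to entinostat at 1, the Dox_DMSO library lay at 0.342 and the NoDox_Entinostat library at 0.940. The first value lay above the limit set beforehand against a swap, so that test did not decide. With the trend removed, a test chosen after the result was seen, they lay at 0.187 and 0.950, which argues against a swap. RNA from B cells, T and NK cells, neutrophils or stromal and endothelial cells is argued against as well. The genes of those lists took 1.07 and 0.962 times the share seen in the other libraries of the same groups. Other cell types were not covered by this test. In the Dox_Entinostat libraries (mean slope -0.26) a length bias of the libraries cannot be told apart from the combined treatment, because all 3 share it, and what set the first libraries apart stays open.

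Rises made up 83.7% of genes called and changed at least 2-fold by entinostat without doxycycline. TMM scaling as the cause is argued against, since library size alone gave 93.2%, and so is a length and GC trend, since its removal left 84.1%. Among the 5017 genes with the highest expression (log2 CPM of at least 5.35), 17.7% of such genes rose (86 up and 400 down). The excess of rises thus lay in genes below that level. These include genes near the detection floor, where a fall is hard to detect, and genes well above the floor. With a filter of 1 CPM in at least 3 libraries, rises still made up 82.5% (2539 up and 540 down). That filter can keep genes silent in DMSO, so neither value isolates genes near the floor, and their part stays open. Release of silent genes by the inhibitor is the biological explanation the design gives, and it was not tested apart from an effect of the detection floor.

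Genes up in experiment 1 tended to rise with entinostat (odds ratio 3.39) and to have negative interactions. Shared expression level is argued against as the cause of the overlap, since the common odds ratio within 10 expression bins was 4.18 (3.45 to 5.07). For the interaction, the difference in medians was -0.42 with the length and GC trend removed, so the fitted trend alone did not account for it. A wider bias of the libraries is not excluded, because deviations of the first Dox_DMSO and NoDox_Entinostat libraries still correlated at 0.924 after the removal. Choice by entinostat effect does not enter, since these genes were chosen from experiment 1 alone. Their difference of -0.55 as deposited is the pattern itself and no test of it. With the replicate block in both fits the overlap fell under its expectation (odds ratio 0.867), and genes down in experiment 1 also rose with entinostat in excess (2.24, 1.92 to 2.62, within bins). A general response of changeable genes to both treatments stays open, and shared repression by SPI1 and histone deacetylases was not tested apart from it.

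Other splits of the libraries were fitted for each count. For each comparison of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split called 1881 genes in experiment 1, 1401 with doxycycline in DMSO, 3614 with doxycycline in entinostat, 7099 with entinostat without doxycycline and 9595 with it, and the highest of the other splits 0 in each by edgeR, so 1 of 10 was as large. Each other split mixes treated and untreated libraries within its groups. The treatment effect then adds to the spread within groups and lowers the calls, so these 0 counts are no baseline for chance. For the calls shared by the experiments (996) and the genes up with doxycycline and entinostat (341), other splits of experiment 1 gave 0. This follows from their 0 calls and is no further check of the overlaps. In experiment 1, whose libraries met the limit for pairing, 4 of the 10 splits part all 3 same-number pairs, and the others among them called 0 as well.

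The list test behaved differently in these splits. As many lists passed in 6 of 10 splits in experiment 1 (10 in the real split, 12 in the highest other), 6 in DMSO (8 and 12), 3 for entinostat without doxycycline (17 and 18), 1 with doxycycline (17 and 14) and 7 for doxycycline in entinostat (9 and 15). For the genes up in experiment 1, as small a p came in 1 split in DMSO (4.12e-84, and 5.48e-27 as the smallest other), 3 for entinostat without doxycycline (0.000266 and 1.08e-05), 9 with it (0.531 and 0.000109) and 5 for doxycycline in entinostat (9.49e-16 and 5.57e-24). In 4 of these 5 comparisons camera with a preset correlation thus passed as many lists in other splits, where 0 genes were called by edgeR. The groups of each other split hold unequal numbers of treated libraries, so its contrast keeps part of the treatment effect. These passes are therefore no measure of chance.

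For the interaction, 100 of 200 splits were drawn. As many as 41 genes were called in 8 of them, up to 3415, so chance is not excluded. Of the 7 others, 6 exchange libraries within the entinostat arm alone, so that their contrast holds the doxycycline effect itself, and 1 exchanges libraries in both arms and called 2398. Among the 49 splits that exchange equally in both arms, 2 called as many. As many as 5 lists passed in 81 splits (up to 16), and in 30 of those 49, so chance is not excluded for the lists. As small a p for the genes up in experiment 1 (7.33e-20) came in 31 of the 100 splits (down to 3.34e-84). The 30 others all exchange unequally, and among the 49, a restriction chosen after the result was seen, the smallest other p was 9.11e-13. The split with 2398 calls points to a structure of the libraries besides the groups.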

How the results depend on the processing

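The counts minus 1, the removed length and GC trend (alone or with the block) and the fits without the first Dox_DMSO and NoDox_Entinostat libraries were chosen after seeing the data. No named gene reversed in any setting. Pooled over the fits with 1 library left out, 273 results of named genes lost their call, 34 gained one and 6214 kept their status, called or not. These counts pool many fits, so they cannot be set beside the counts of the other settings. With library size alone 10 results of named genes lost their call and 5 gained one (a gene counts once per contrast), without a filter 22 and 8, with limma-voom 6 and 1, and with DESeq2 0 and 9. Library size alone moved the median of all genes from 0.07 to 0.32 for entinostat without doxycycline. Of the list results, 65 lost their call with an estimated correlation and 107 kept their status, nearly all of them not called in the main fit. At the depth and 3 libraries per group of these data, 2-fold changes were recovered in 4.48% of simulated cases for the interaction, and depth was not varied.

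In experiment 1, 817 called genes changed at least 2-fold, 1103 passed without a filter, where more genes are tested, 7027 with the replicates paired as a block and 7479 with the block and the removed length and GC trend. Keeping only called genes changed at least 2-fold left 4547 for entinostat without doxycycline and 2021 for doxycycline in entinostat, by its construction. In experiment 1 the block changed the calls of Gata1, Klf1, Ezh2, Suz12 and the interferon-stimulated list and of no other named gene or list. Experiment 2 missed the limit of 0.1 set for pairing in 4 pairs of groups, and its main fits hold no block. Same-number libraries correlated at 0.00385 to 0.0824 at the lowest in these 4 and at 0.906 and 0.193 in the 2 others. A structure by replicate number is not excluded. Between Dox_DMSO and NoDox_Entinostat, same-number libraries correlated at 0.956, 0.925 and 0.906, and libraries of other numbers at up to 0.844. Of 6 libraries, 4 to 6 correlated best with their own number in each pair of groups of experiment 2, and 5 in experiment 1. With the block, 6115 genes passed for doxycycline in entinostat (at least 2-fold, 1346 up and 1140 down) and 177 in the interaction (73 positive and 104 negative), the shared calls of the experiments were 26.8%, the genes up with doxycycline and entinostat 828, and the genes down in experiment 1 passed for entinostat without doxycycline (adjusted p = 0.0329). With the length and GC trend removed, 2188 genes passed for doxycycline in DMSO, 99 in the interaction (38 of the 41 kept) and 2 lists in the interaction. The mitochondrially encoded list then reversed, at adjusted p = 0.0156 for entinostat with doxycycline and 0.522 for doxycycline in entinostat, and the genes down in experiment 1 had 0.0426 for entinostat without doxycycline. Without the first Dox_DMSO and NoDox_Entinostat libraries, 4846 genes passed in DMSO, 9569 for doxycycline in entinostat and 7972 in the interaction (the 41 kept), 81.3% of calls were shared by the experiments and 9 lists passed in the interaction. The genes down in experiment 1 then had 0.00318 for entinostat without doxycycline, 0.164 with it and 0.301 in the interaction. The interaction held 206 genes without a filter and 235 with DESeq2, and 3 lists with a filter of 1 CPM. The genes up with doxycycline and entinostat numbered 120 at a threshold of 0.01 and 198 at a change of at least 2-fold in both. With an estimated correlation, 0 lists passed in experiment 1, 1 in DMSO, and 0 for entinostat without doxycycline, entinostat with doxycycline, doxycycline in entinostat and the interaction; the genes up in experiment 1 had 0.516 for entinostat without doxycycline, and those down in experiment 1 had 0.837 with doxycycline and 0.150 in the interaction. The genes down in experiment 1 had 0.0464 for entinostat without doxycycline with library size alone and 0.00262 with a filter of 1 CPM. Where no construction is named, the cause was not tested.

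With each library left out in turn, the calls ranged from 684 to 1508 in experiment 1, 862 to 1741 in DMSO, 6009 to 8193 for entinostat without doxycycline, 8315 to 10947 with it, 994 to 7583 for doxycycline in entinostat and 9 to 3061 in the interaction. The shared calls of the experiments ranged from 37.6% to 82.7%, the genes up with doxycycline and entinostat from 129 to 359, and the lists in the interaction from 5 to 13. The genes down in experiment 1 ranged from an adjusted p of 0.00659 to 0.246 for entinostat without doxycycline and from 0.0219 to 0.123 with it.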

Other observations

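Another 5 lists passed the test for doxycycline in entinostat-treated cells. Stem and progenitor regulators fell in 8 of 13 cases and rose in 0 (9 and 0 adjusted over the list alone; adjusted p = 0.00187, and 0.757 with an estimated correlation), with the adhesion receptor Cd44 at -1.66, Hhex at -1.11 and Myb at -0.99. Mast cell and basophil genes fell in 6 of 9 cases and rose in 0 (7 and 0 adjusted over the list alone; adjusted p = 0.00119, and 0.0887 with an estimated correlation), with the histidine decarboxylase gene Hdc at -1.72 ± 0.23. Without the first Dox_DMSO and NoDox_Entinostat libraries the mast cell list had an adjusted p of 0.0887. Red cell membrane genes rose in 7 of 27 cases and fell in 2 (8 and 2 adjusted over the list alone; adjusted p = 0.0144, and 0.764 with an estimated correlation), and lost this call without the first NoDox_Entinostat library (0.123), or without that and the first Dox_DMSO library (0.136). HDAC and corepressor subunits fell in 5 of 34 cases and rose in 0 (4 and 0 adjusted over the list alone; adjusted p = 0.0226, and 0.764 with an estimated correlation), a call lost without the second (0.0800) or the third NoDox_Entinostat library (0.0752) at 0.0568 with a filter of 1 CPM, and at 0.693 with the length and GC trend removed. The mitochondrially encoded list passed upwards with 0 of 11 members called by edgeR, DESeq2 or limma-voom and 2 at an unadjusted edgeR p under 0.05 (adjusted p = 0.0218, and 0.764 with an estimated correlation) and lost its call without the first Dox_Entinostat (0.0519) or the second (0.0641) or the third NoDox_Entinostat library (0.0609). The direction of this list reversed, without a call, when the length and GC trend was removed.

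Entinostat widened the range of genes detected. Genes at the minimum count in a library numbered 9192 ± 104 in NoDox_DMSO and 9544 ± 50.1 in Dox_DMSO, and 6051 ± 73.4 in NoDox_Entinostat and 6310 ± 418 in Dox_Entinostat (mean ± SD, 3 libraries each). With doxycycline present, entinostat changed the amino acid transporter gene Slc7a5 by -2.28, squalene epoxidase Sqle by -2.38 and the erythropoietin receptor Epor by -1.92 ± 0.13.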
